A study of Arabidopsis thaliana with 9 samples.

How the data were processed

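Gene expression was measured in Arabidopsis thaliana seedlings without roots, at 10 DAS in the labels' unit, for the accessions Col and C24 and their F1 hybrid, with 3 biological replicates of each and 1 array per replicate, 9 arrays in all. Per the labels, plants grew at 22 degrees with a 16 h and 8 h photoperiod, total RNA was labelled with biotin, and each sample was hybridised to a 1-colour Affymetrix array. The labels call the replicates biological and do not say how the plants were grouped into samples, nor which accession was the mother of the F1.

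The deposited values are probe-set intensities on a linear scale, 1 per probe set and array, and GCOS is the software named in the submitters' processing notes. Its version and settings are not given in the sources used here. The mean of each deposited column after leaving out 2% of its values at each end lay between 150.01 and 150.02, so each array had been scaled to the same trimmed mean. Values ran from 0.0104 to 9775. No detection calls were used here, so a signal near the bottom of the scale was not separated from background, and the number of arrays limits the precision of every comparison.

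The median log2 signal of the 9 deposited columns spanned 0.24, above the limit of 0.2 fixed before the data were examined, so the arrays were quantile normalized with limma 3.58.1 in R 4.3.3 after the 64 control probe sets had been set aside. Values were then set to at least 1 and log2 was taken. Of 22746 probe sets, those with a mean log2 signal under the 30th percentile, a signal of about 11.1, were left out, which left 15922. One limma fit with a mean per group over all 9 arrays gave the contrasts C24 against Col, F1 against Col and F1 against C24 (lmFit and eBayes with a trend, Benjamini-Hochberg adjustment, threshold 0.05). The mid-parent value was the arithmetic mean of both parents on the linear scale, with its variance by the delta method. Log2 differences are followed by their standard error; signals are means of normalized linear values with their SD over 3 arrays. Folds come from the fitted log2 means, and no fold is given where the dimmer group lay under or near the filter level of 11.1, since such a signal was not separated from background.

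Genes were named only through the platform annotation, updated by Entrez number to the symbols of the TAIR10.1 assembly. Of the 22746 probe sets, 13513 named 1 gene, 503 named several and 8730 were not listed and are unnamed here; 13436 of the first kind matched a locus. Among the 15922 tested, 8809 named 1 gene, for 8727 genes. Of 585 loci in 27 gene lists fixed before the data were examined, 87 were named by a probe set and 80 were tested, so that 5 lists reached the minimum of 5 tested genes. A further 22 lists were therefore written after the gene names, the control probe sets and the correlations between arrays had been seen, but before any comparison between groups of a listed gene was computed, and 21 of these were tested. Lists were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, using the brightest probe set of each gene, with adjustment over the fixed and the later lists separately.

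Named genes followed a rule fixed before the data were examined. For C24 against Col and for the mid-parent comparison these were the 6 highest and 6 lowest changes past the threshold that named 1 gene, with the brighter group above the median signal and no overlap between the arrays of both groups, or with all 3 F1 arrays on one side of the mid-parent value. For F1 against a single parent the 3 highest and 3 lowest were taken, and for F1 outside both parents up to 5 in each direction. Up to 4 genes of each list with the smallest p were added, and 10 genes were to be reported whenever measured; 2 of these, GI and PORB, were named by a tested probe set.

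On simulated arrays made from the real means and spreads, with 200 of 15922 probe sets changed, C24 against Col recovered 13.4% of 1.5-fold, 73.1% of 2-fold and 95.5% of 4-fold changes, and the mid-parent comparison recovered 16.4%, 83.6% and 95.5%. The changed probe sets were drawn from the brighter part of the range. There were 4 and 7 false calls. A list of genes shifted by 0.5 in log2 was called, with 0 others of the 26 lists, and 0 were called with no shift. The noise was drawn separately for each probe set, so the genes of a simulated list were uncorrelated. In the real data the estimated correlation was 0.65 for plastid-encoded genes and 0.67 for flavonoid and anthocyanin genes. The simulation thus does not test false calls for lists of correlated genes.

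After seeing the data, an additive F1 was also simulated from the fitted parents with the deviations of real arrays from their group means, scaled up for the fitted means and shuffled 100 times, either over whole arrays or among the groups within each replicate number.

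Arrays carrying the same replicate number were compared by the correlation of their deviations from the group means. It was over 0.1 in all 3 pairs of Col and C24 (0.15 to 0.49) and of Col and F1 (0.11 to 0.47). By that limit the numbers were taken to pair these, but the main fit held no pairing, which entered only as a replicate block. In C24 and F1 the correlation was over 0.1 in 2 of the 3 pairs (lowest 0.013), and these groups were not taken as paired. Only replicate 1 stood clearly apart, at 0.49, 0.47 and 0.46 in the 3 pairs of groups. Deviations of 3 arrays from their mean sum to 0, so a shift of replicate 1 also draws replicates 2 and 3 together. Passing 0.1 therefore cannot show a pairing of replicates 2 and 3. Pairs of different numbers reached 0.12 for Col and C24, 0.18 for Col and F1 and 0.20 for C24 and F1. A pairing of replicates 2 and 3 by number is thus not borne out for Col and F1. Alternatives were a replicate block, scaling to a common median, no filter, a filter at the 50th percentile, 16 added before log2, no variance trend, only the groups compared, a log2-scale mid-parent value, a log2-scale position, an estimated list correlation, and each array left out in turn. The deposited scaling as it stands was added after seeing the data. No coordinates are given, since the build behind the array is not given in the sources used here.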

Results

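Signals of 22746 probe sets were compared between the Arabidopsis accessions Col and C24 and their F1 hybrid, with 3 arrays per group from seedlings without roots. Arrays of one group correlated at 0.94 to 0.97 over the tested probe sets, and arrays of Col and C24 at 0.90 to 0.93. The first principal component held 38.9% of the variance and placed Col at -39.4 to -37.1, F1 at -8.22 to -3.26 and C24 at 41.2 to 47.4. The second held 19.4% and set replicate 1 of every group, at 29.4 to 34.4, apart from the others, all below 0.

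**Figure D1:**
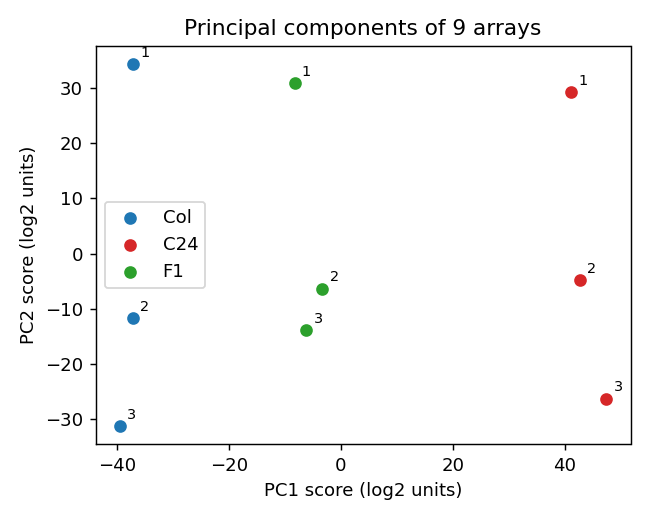
Scores of the 9 arrays on the first and second principal components of the tested log2 signals, in log2 units; colours mark the groups and digits the replicate. F1 arrays lie between the parents, at -8.22 to -3.26 on the first component.

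The comparison of C24 with Col asks how far the parents differ. ECS1, a gene of a small secreted protein, had a signal of 4422 ± 949 in Col and 16.2 ± 1.33 in C24 (SD, n = 3). QQS, a gene known for its effect on leaf starch, was at 258 ± 46.3 in Col and 2.98 ± 2.98 in C24. AT4G19500, which encodes an immune receptor of the nucleotide-binding leucine-rich repeat class (NLR), was at 139.6 ± 7.35 in Col and 0.843 ± 0.134 in C24. In the other direction AT4G29200 was at 7.86 ± 0.799 in Col and 1253 ± 63.9 in C24, and AT1G61500, a gene of a receptor-like kinase, was at 14.2 ± 6.27 in Col and 471 ± 162 in C24.

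The remaining lowest genes in C24 by the fixed rule were AT1G76960 (348 ± 42.2 in Col, 0.497 ± 0.199 in C24), AT1G23960 (277 ± 43.2 and 1.36 ± 0.415) and AT1G35612 (216 ± 87.3 and 2.86 ± 3.26). The remaining highest were AT3G48640 (0.938 ± 0.24 in Col, 161 ± 33.1 in C24), AT1G63540 (1.17 ± 0.405 and 64.01 ± 9.87), AT5G34920 (6.37 ± 4.37 and 123.8 ± 19.7) and AT2G44380 (3.02 ± 2.06 and 59.6 ± 17.8). All of these passed the limma test, with adjusted p of at most 0.000797, the value for AT5G34920. A very low signal in C24 may come from sequence differences from the Col-based probes as well as from expression, which these data cannot tell apart. In all, 567 probe sets were higher and 781 lower in C24, 8.47% of those tested, and 781 of the 1348 differed at least 2-fold. Which direction held more depended on the scaling, with 42.1% of calls higher in C24 here, 51.8% with a common median and 34.3% with the deposited scaling. With replicate number as a block, 756 probe sets were higher and 979 lower in C24. The 12 genes named here kept their call whichever array was left out, wherever they stayed above the filter. The count higher in C24 was 318 without Col replicate 2 and to 328, 288 and 345 without C24 replicates 1, 2 and 3, and the count lower was 485 without Col replicate 2.

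Among the fixed lists, that of flavonoid and anthocyanin genes tested lower in C24 at the preset correlation but not with an estimated correlation. DFR, which encodes dihydroflavonol reductase, was at 692.7 ± 290.5 in Col and 148 ± 5.07 in C24 (4.38-fold, adjusted p = 0.00268), and UGT78D1, a flavonol glycosyltransferase gene, was 5.95-fold lower (adjusted p = 0.00177). UF3GT and AT4G14090 had log2 differences of -2.43 ± 0.76 and -2.42 ± 0.91 that did not pass in limma without a replicate block (adjusted p = 0.0833 and 0.151), though UF3GT passed without Col replicate 3 (0.0251). Both varied widely between replicates and were lower in C24 at each replicate number. UF3GT was at 569, 188 and 64.2 in Col against 65.2, 35.0 and 19.2 in C24, and AT4G14090 at 391, 127 and 67 against 74.0, 49.1 and 5.96. Of 5 genes, 2 were lower and 0 higher over all probe sets, and 4 were lower adjusted over the list alone. The camera test of the list gave an adjusted p of 0.00266, and adjusted p = 0.44 with an estimated correlation.

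The other tested fixed lists did not pass: photosystem and electron transport (adjusted p = 0.848, 0 of 5 genes called), chlorophyll biosynthesis (0.848, 0 of 9), cytosolic ribosome (0.162, 1 of 5 higher; 0.0399 with the deposited scaling) and cell wall expansion (0.965, 0 of 5). In the cytosolic ribosome list AT2G19730 was 1.27-fold higher in C24 (adjusted p = 0.0311), a call lost without any one of the Col or C24 arrays (adjusted p up to 0.0982, without C24 replicate 3). PSAN, a photosystem I subunit gene, was at 3555 ± 193.8 in Col and 3895 ± 166.8 in C24, and CHLM of chlorophyll synthesis at 2750 ± 97.1 and 2271 ± 256.5, neither past the test.

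In lists too short for a list test, 3 of 4 cold and abscisic acid genes were lower in C24: LTI30 at 14.7 ± 13.8 against 76.9 ± 10.4, COR15B 1.60-fold and COR15A 1.68-fold. APL3, a subunit of the enzyme that makes ADP-glucose for starch, was 4.11-fold lower in C24, and SBE2.2, a starch branching enzyme, 1.45-fold lower. AT5G48570, from the heat shock list, was lower, at 13.1 ± 4.57 against 49.1 ± 9.03. GRX480, a glutaredoxin of the salicylic acid response, was higher in C24, at 53.7 ± 15.02 against 13.5 ± 0.297, as were the amino acid aminotransferase gene BCAT4 of glucosinolate synthesis (1.97-fold) and the floral repressor gene SNZ (3.08-fold). PYK10, a beta-glucosidase from the list of root markers, was 4.77-fold higher in C24, at 1362 ± 427 against 278.8 ± 37.8, while EXPA18 of the same list was at 9.60 ± 3.00 against 19.9 ± 6.69 (adjusted p = 0.122). Single arrays left out took several of these over the threshold. COR15B was lost without Col replicate 1 or 2 or C24 replicate 1 or 2 (adjusted p up to 0.101), COR15A without Col replicate 1 or 2, F1 replicate 1 or 2 or any C24 array (up to 0.135), and SBE2.2 without Col replicate 2 or 3 or any C24 array (up to 0.108). BCAT4 was lost without Col replicate 2 or 3, F1 replicate 1 or 2 or any C24 array (up to 0.121), and SNZ without Col replicate 2 or 3, F1 replicate 2 or any C24 array (up to 0.159). Over all fixed lists 5 of 80 genes were higher and 8 lower. GI, a clock gene, was at 262 ± 14.1 in Col, 300.5 ± 22.6 in C24 and 265 ± 40.2 in F1, and PORB of chlorophyll synthesis at 3232 ± 119.8, 3720 ± 490.8 and 3036 ± 974; neither passed any comparison.

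Of the lists written after the gene names were seen, 6 passed. Pathogen- and salicylate-induced genes tested higher in C24 (adjusted p = 0.00513, but adjusted p = 0.552 with an estimated correlation), with 4 of 11 genes higher and 0 lower, among them the chitinase gene AT2G43570 (symbol CHI) at 13.3 ± 1.26 in Col and 147.6 ± 55.4 in C24 and AT5G55450, a lipid transfer protein gene, 4.27-fold higher (lost without any Col array or C24 replicate 1 or 2, adjusted p up to 0.078). Adjusted over the list alone, 8 of the 11 were higher. NLR immune receptors tested lower (0.00673, but adjusted p = 0.552 with an estimated correlation), with 11 of 49 genes lower and 4 higher. Their median log2 was -0.12 and their mean -0.41. AT5G45510 was 6.51-fold and AT3G44630 8.07-fold lower. Here too, sequence differences from the Col-based probes cannot be told apart from expression. Glutathione transferases of the GSTU class tested higher (0.0334, but adjusted p = 0.552 with an estimated correlation; 3 of 7 genes), with GSTU26 4.55-fold higher. Cytosolic ribosomal protein genes tested higher (0.0171, but adjusted p = 0.586 with an estimated correlation; 7 of 120 higher, 3 lower) by a median log2 of 0.17. Plastid-encoded transcripts tested lower (0.0171, but adjusted p = 0.816 with an estimated correlation; 5 of 62 lower, 2 higher), with psbL 3.45-fold and psbE 2.95-fold lower in C24, where the 25S ribosomal RNA control was at 118 ± 89.2 against 1464 ± 981 in Col. Serine carboxypeptidase-like genes tested lower (0.00673, but adjusted p = 0.552 with an estimated correlation) although their median log2 was 0.02 and their mean -0.37; 1 of 15 was called, scpl42, at 249.9 ± 28.7 in Col and 8.88 ± 0.57 in C24. The NLR list was also lost with the filter at the 50th percentile (adjusted p = 0.254), and the plastid list with the deposited scaling (0.121). The ribosomal and GSTU lists were lost with no variance trend (0.0767 each) and the GSTU list with no filter (0.0573). The plastid list was lost without Col replicate 2 (adjusted p = 0.0708) and without C24 replicate 3 (0.0601), and the ribosomal list without Col replicate 2 (0.0602) or C24 replicate 2 (0.117). The GSTU list was lost without Col replicate 2 (0.0602) or C24 replicates 1 (0.0688) or 2 (0.0555).

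The F1 was then compared with each parent. Against Col it was higher for AT4G29200 (776 ± 58.4), for AT1G61500 (270.2 ± 80.4) and for AT5G34920 (64.1 ± 3.89), all of them higher in C24 than in Col as well. It was lower for AT1G67865, at 103.7 ± 46.01 against 790.7 ± 264 in Col and 20.6 ± 4.74 in C24, for AT1G20390, at 7.73 ± 4.79 against 96.6 ± 15.4 in Col and 7.42 ± 4.76 in C24, and for AT1G76960 (3.56-fold). Against C24 the F1 was higher for ECS1 (3383 ± 305), AT1G23960 (171.8 ± 28.6) and AT1G76960 (98.02 ± 13.3), and lower for the chitinase gene CHI (14.4 ± 2.77 against 147.6 ± 55.4), for CML41, a calmodulin-like gene (11.8 ± 2.77 against 51.7 ± 4.97), and for AT1G52100 (3.86-fold). The call of AT5G34920 against Col was lost without C24 replicate 2 or any F1 array (adjusted p up to 0.117) and that of AT1G20390 without any Col array or F1 replicate 2 or 3 (up to 0.137). Of the 80 fixed-list genes, UGT78D1 and AT5G48570 were higher in F1 than in C24 (the first lost without C24 replicate 1 or 2 or F1 replicate 1 or 3, adjusted p up to 0.0807, the second without F1 replicate 2 or 3, up to 0.0832) and 0 passed against Col, where 7 had an unadjusted p under 0.05 in limma.

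Against Col 65 probe sets were higher and 16 lower in F1, and against C24 271 were higher and 60 lower. With replicate number as a block, 32 were lower than in Col and 97 lower than in C24, and with a common median 100 were lower than in C24. Leaving out F1 replicates 1, 2 or 3 left 32, 30 and 35 higher and 7, 8 and 7 lower than in Col. Leaving out Col replicates 1, 2 or 3 left 8, 6 and 9 lower. Against C24 the count higher was 153 and 145 without F1 replicates 1 and 2 and the count lower 22 and 24. Without C24 replicates 1, 2 and 3 that count was 27, 21 and 30.

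Most of these probe sets also differed between the parents. Of the 271 higher in F1 than in C24, 262 were higher in Col than in C24, where independent lists would share 13.3, and of the 65 higher in F1 than in Col, 64 were higher in C24, where independent lists would share 2.31. Of the 60 lower than in C24, 54 were higher in C24 than in Col, and all 16 lower than in Col were higher in Col than in C24. The comparisons share arrays, which independent lists do not allow for. With an F1 put at the mid-parent of the fitted parents and the deviations of real arrays shuffled within each replicate number, 94 to 312, 30 to 202, 2 to 96 and 0 to 72 were shared in 100 shuffles, which take in all 4 observed overlaps. With noise drawn separately for each probe set the additive F1 shared 315 to 360, 159 to 203, 53 to 71 and 55 to 87 in 20 simulations, above 3 of the 4 observed. Such noise leaves out the deviations that probe sets of an array share.

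The position of F1 between the parents was measured where they differed at least 2-fold, with 0 the Col signal and 1 the C24 signal. Sequence differences from the Col-based probes would also place F1 between the parents for probe sets higher in Col. These data cannot tell that apart from expression. For the 479 probe sets higher in Col the median was 0.47 with quartiles of 0.33 and 0.58, and for the 302 higher in C24 it was 0.40 with quartiles of 0.25 and 0.56. The medians of the 3 F1 arrays were 0.48, 0.44 and 0.48 for the first set and 0.40, 0.39 and 0.42 for the second. With an F1 put at the mid-parent and array deviations shuffled within each replicate number, the medians were 0.52 on average (0.455 to 0.588 in 100 shuffles) and 0.48 (0.369 to 0.619), which take in both observed medians. With noise drawn separately for each probe set they were 0.500 to 0.525 and 0.454 to 0.503 in 20 simulations, above both observed medians. Whether the F1 departed from the mid-parent thus depends on the noise assumed. The first median was 0.50 without Col replicate 3. On the log2 scale the medians were 0.31 and 0.56.

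**Figure D2:**
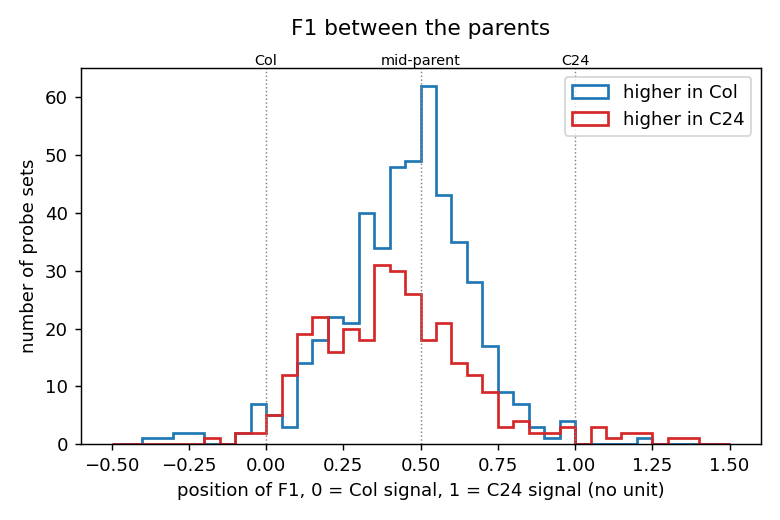
Number of probe sets at each position of the F1 between the parents on the linear scale (0 Col, 1 C24, no unit), for probe sets at least 2-fold apart and past the limma test. The medians are 0.47 for the 479 higher in Col and 0.40 for the 302 higher in C24.

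Against the mid-parent value, the measure of additive expression, 1 probe set was higher and 5 were lower in F1. Where Col-based probes miss the C24 sequence, the Col copy in F1 could alone give a signal near this value. A signal near the mid-parent value thus need not be additive expression. AT3G26450 was at 541.5 ± 49.9 in F1 against 354.5 ± 35.9 in Col and 182.8 ± 9.25 in C24, a log2 difference of 1.01 ± 0.12 from the mid-parent value (adjusted p = 0.0254). CHI was at 14.4 ± 2.77 in F1, like Col at 13.3 and unlike C24 at 147.6. The other 4, which name no gene here and were chosen after their values were seen, were at 30.5 ± 11.5 in Col, 1354 ± 634 in C24 and 54.6 ± 9.38 in F1, at 16.1 ± 1.07, 181 ± 51.4 and 26.9 ± 3.66, at 12.99 ± 1.61, 144.8 ± 11.04 and 26.01 ± 5.17, and at 55.8 ± 10.98, 13.3 ± 5.64 and 4.06 ± 1.3. All 6 had the adjusted p of 0.0254.

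With replicate number as a block, 0 of the 6 passed in limma and 0 others did, and with the log2-scale mid-parent value there were 34 calls. An additive F1 with shuffled array deviations gave 0 calls in 100 shuffles within each replicate number and 0 to 1943 in 100 shuffles of whole arrays. At an unadjusted p under 0.05 there were 803 probe sets without the block, against 796 from chance alone. The 6 calls became 1 without Col replicate 2 or 3, 2 without C24 replicate 1, and 0 without C24 replicate 2 or any one of the F1 arrays. Of the named genes, AT3G26450 kept its call only without Col replicate 1 (adjusted p up to 0.167 otherwise) and CHI only without C24 replicate 3 (up to 0.187). Of the 80 fixed-list genes 0 passed in limma and 4 had an unadjusted p under 0.05, among them PDF1.2b, a defensin gene, at 57.1 ± 9.77 in F1 against 18.97 ± 7.21 in Col and 27.6 ± 9.97 in C24 (adjusted p = 0.6).

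Outside the range of both parents, 1 probe set was higher and 0 were lower in F1. AR781 was at 180.9 ± 24.9 in F1, 78.5 ± 15.2 in Col and 84.3 ± 19.1 in C24. Independent lists would share 1.11 above and 0.0603 below both parents, and an additive F1 gave 0 to 2 in each direction over 100 shuffles of array deviations within each replicate number, and 0 to 384 above and 0 to 433 below over 100 shuffles of whole arrays. The call of AR781 was lost without any one of the Col or F1 arrays and without C24 replicate 1 or 3 (adjusted p against Col up to 0.157, without F1 replicate 3). The count was 0 without any one of the Col or F1 arrays and 1, for another probe set, without C24 replicate 1 or 3.

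Of the gene lists, none of the fixed ones differed between F1 and the mid-parent value (adjusted p = 0.938 for each of the 5). With a common median the photosystem (0.0495) and cytosolic ribosome (0.0341) lists passed, both lower, and with the deposited scaling these 2 (0.0107 each) and chlorophyll biosynthesis (0.043). Pathogen- and salicylate-induced genes were lower (adjusted p = 0.000117; 1 of 11 genes, CHI), and adjusted p = 0.729 with an estimated correlation; adjusted over the list alone, 2 genes were lower. Their median deviation from the 9-array mean was -0.91, -0.24 and 0.45 on the F1 arrays, -1.06, -0.07 and -0.23 on the Col arrays and 1.08, 0.93 and 0.63 on the C24 arrays. Plastid-encoded transcripts also tested lower (adjusted p = 2.14e-08), with 0 of 62 called and adjusted p = 0.79 with an estimated correlation. The estimated correlation was used with the log2-scale mid-parent value. At the preset correlation the pathogen and plastid lists passed with that value too. On F1 replicate 2 the median deviation of the plastid-encoded genes was -1.82, against 0.21 and 0.43 on the other F1 arrays. Without that array the list median changed from -0.63 to 0.04 (adjusted p = 0.672). The control probe set for 25S ribosomal RNA was at 41.4 on F1 replicate 2 and at 1380 and 1807 on the other F1 arrays. Leaving out an array brought further lists past the threshold: NLR receptors (0.0267) and histones (0.0181) without Col replicate 2, histones (0.036) and UDP-glycosyltransferases (0.0258) without C24 replicate 1, and autophagy genes (0.039) without F1 replicate 1.

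**Figure D3:**
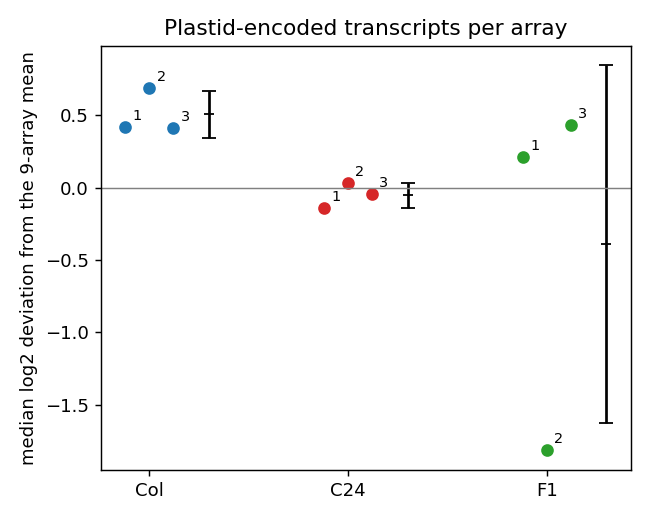
Median log2 deviation of 62 plastid-encoded genes from their 9-array mean, per array, with the replicate as a digit and the mean and SD of each group in black. F1 replicate 2 lies at -1.82 and the other F1 arrays at 0.21 and 0.43.

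The control probe sets for RNA quality were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 arrays against 3. The log2 ratio of 3' to 5' signal was 0.18 ± 0.22 in Col, 0.18 ± 0.23 in C24 and 0.17 ± 0.06 in F1 for GAPDH (exact p = 0.9, Col against C24) and 0.78 ± 0.31, 0.63 ± 0.59 and 0.46 ± 0.08 for ubiquitin (exact p = 0.7). For actin it was 1.77 ± 0.37 in Col, -1.07 ± 1.18 in C24 and 1.43 ± 0.35 in F1 (exact p = 0.1, Col against C24). The actin ratio of 3' to middle signal was 0.59 ± 0.33, -1.65 ± 0.71 and 0.44 ± 0.19 (exact p = 0.1, Col against C24). GAPDH and ubiquitin had no such gap, so the actin ratios need not tell of RNA quality. Their cause was not tested.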

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

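The tests of the plastid-encoded transcripts were chosen only after the result was seen, as were Fisher's test of the Col share by size of difference, the Col share under each scaling and the shuffles of array deviations. The 3' control probe set for actin, which enters none of the comparisons, was 7.82-fold brighter in Col than in C24, at 2799 ± 95.4 against 358 ± 66.2 and 2328 ± 195 in F1 (SD, n = 3), while the 5' actin probe set was at 838 ± 204 and 836 ± 418. The control probe set for 25S ribosomal RNA reached 2464 on the brightest array and was at 41.4 on the dimmest, with 1464 ± 981 in Col, 118 ± 89.2 in C24 and 1076 ± 921 in F1. Both signals appeared in probe sets outside the measurement and were taken up for that reason.

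The lower plastid-encoded transcripts in F1 rest on F1 replicate 2, since the list median was 0.04305 without it, against -0.95 and -1.01 for the same 62 genes without F1 replicate 1 or 3. Over the 9 arrays the median plastid signal rose with the 25S control (Spearman rho = 0.95, permutation p = 0.00034, Pearson r = 0.75, permutation p = 0.00017, 1 relation computed). Without the 2 arrays farthest from the median of the 25S signal r was 0.85. The permutations shuffled all 9 arrays without regard to group. C24 was low in both signals, so these p-values also hold the difference between the groups, and no relation within groups was computed. Differing capture of RNA without poly(A) tails may account for this. Mitochondria-encoded transcripts shifted in F1 by a median of -0.29 against -0.63, and their list of 7 genes did not pass (adjusted p = 0.43). A shift of at least 0.5 of the plastid one was asked for once both medians were known. On F1 replicate 2 the mitochondrial median deviation was -0.037, against 0.22 and 0.12 on replicates 1 and 3. On the same arrays ccb382 was at 24.2 against 177 and 162, and nad4 at 2.23 against 47.6 and 41.4. The dim ccb452 (21.7 against 24.6 and 18.1) and nad1 (17.8 against 16.0 and 14.4) had no such drop. So few genes, with such mixed values, cannot decide the matter, and differing capture stays open. The 25S control was also 12.5-fold dimmer in C24 than in Col, so the lower plastid-encoded transcripts in C24 are open to the same reading. A difference between hybrid and parents, or between the parents, was not tested apart from it.

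More probe sets of 2-fold or more were higher in Col (479) than in C24 (302). The excess stood under each of the 3 scalings, so the choice among them alone did not give it. The percent higher in Col was 61.3 here, 57.97 with a common median (473 against 343, 95% interval 54.5 to 61.4) and 69.2 with the deposited scaling (572 against 255). The interval counts probe sets as independent, though they share arrays, so it does not measure the spread over samples. An offset left by all 3 stays open, since the median log2 difference of 0.03252 decides nothing where quantile normalization sets the centre of each array. Sequence differences from the Col-based probes could also give it and cannot be told apart from expression: the Col share was 62.8% at 2- to 4-fold and 58.3% at 4-fold and more (Fisher's exact p = 0.2418, two-sided), and the planned test on partner probe sets was void, with 6 probe sets higher in Col and 0 higher in C24 that had a partner. A share that did not rise was to argue against sequence differences, but the 95% intervals of 58.5% to 67% and 52% to 64.4% overlap. Among calls under 2-fold the share was lower, 53.3% (302 against 265, 49.1% to 57.4%), and at 16-fold and more it was 63.0% (34 against 20). These intervals too count probe sets as independent. The shares thus decided nothing, and a true difference between the parents stays open, untested. An offset was not tested against the control probe sets from other organisms. On the deposited scale the 5' cre set was at 2466 ± 60.1 in Col and 3194 ± 298 in C24, without overlap. It was at 2423, 2483 and 1490 on F1 replicates 1, 2 and 3. The 3' dap set was at 222 ± 72.1 in Col and 240 ± 61.1 in C24, with overlap.

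On the linear scale the F1 lay at a median position of 0.47 and 0.40 between the parents where these differed at least 2-fold. An additive F1 with array deviations shuffled within each replicate number gave medians at or below these in 5 and 6 of 100 shuffles, while noise drawn separately for each probe set, which leaves out deviations shared within an array, gave 0.500 to 0.525 and 0.454 to 0.503 in 20 simulations; a distance from the mid-parent thus depends on the noise assumed. Signal compression would carry the F1 toward the higher parent in both sets. The median share of the way was 0.53 for probe sets higher in Col and 0.4032 for those higher in C24. The latter fell short of 0.5 by less than 2 SD of the shuffles of whole arrays (0.118). It fell short of 0.5 by more than 2 SD of the shuffles within each replicate number, whose SD was 0.0439. An additive F1 itself averaged 0.481 in those shuffles, and the value lay less than 2 SD below that. A share at or below 0.5 in 1 of the 2 directions was to count against compression. That bound was met and was set aside after the values were seen, since it leaves out the spread. The value thus decides nothing, and compression may still be present. On the log2 scale the positions were 0.31 and 0.56, both toward the higher parent, where the mid-parent of linear signals also lies. The first position was 0.50 without Col replicate 3, and the positions were 0.44 and 0.43 with the deposited scaling.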

How the results depend on the processing

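The deposited scaling and the lists written after the gene names were seen were chosen after seeing the data, as was the look at which arrays the splits below hold. With the replicate block F1 against Col gave 32 lower, F1 against C24 97 lower, the mid-parent comparison 0 (803 probe sets had an unadjusted p under 0.05 in limma without it) and F1 outside both parents 2; 3 of 9 arrays correlated best with their own number in both other groups, and the block changed no list call. With a common median F1 against C24 gave 100 lower, and 2 fixed and 6 later lists were called against the mid-parent value; the median log2 difference of C24 and Col was then 0.10. With no filter there were 3 mid-parent calls and 2 outside both parents. With the filter at the 50th percentile, which tests fewer probe sets, C24 against Col gave 377 higher, F1 against Col 43 higher, F1 against C24 28 lower, the mid-parent comparison 2 and 1 later list, and the position for probe sets higher in C24 was 0.434. With 16 added before log2, F1 gave 27 lower than Col and 91 lower than C24. Without a variance trend 0 probe sets lay outside both parents. With only the groups compared, 33 were higher in F1 than in Col. The log2-scale mid-parent value, which lies below the linear one, gave 34 calls and 4 later lists. With an estimated correlation 0 fixed and 0 later lists were called in C24 against Col and 0 later lists against the mid-parent value. On the log2 scale the positions were 0.31 and 0.558. With the deposited scaling 0 lay outside both parents, the positions were 0.439 and 0.430, 2 fixed lists were called in C24 against Col, and 3 fixed and 4 later lists against the mid-parent value. Apart from those named, the cause was not tested.

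With each array left out in turn, which leaves fewer samples, C24 against Col gave 288 to 549 higher and 485 to 771 lower, F1 against Col 30 to 61 and 6 to 20, F1 against C24 145 to 265 and 21 to 75, the mid-parent comparison 0 to 5 and F1 outside both parents 0 to 1. The positions were 0.449 to 0.5 and 0.376 to 0.433, the later lists called 3 to 6 in C24 against Col and 1 to 4 against the mid-parent value. The median of the serine carboxypeptidase-like list turned to -0.0231 with the deposited scaling and ran from -0.0944 to 0.0392 with 1 array left out, below 0 without Col replicate 2 (-0.00424) or 3 (-0.00362) or C24 replicate 2 (-0.00923) or 3. The plastid-encoded list against the mid-parent value ran from -0.98 to 0.043, the latter without F1 replicate 2; the filter was redrawn on the arrays left, which is not so for the fixed 62 genes weighed above.

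Splits of the same arrays were counted too. For C24 against Col (1348 calls), F1 against Col (81) and F1 against C24 (331) only 1 of 10 splits, the real one, gave as many, the highest other gave 0, and 10 splits are too few for a share under 0.05. For the 7 lists in C24 against Col it was 1 of 10, with 3 in the highest other. Chance could not be excluded for the 6 mid-parent calls (9 of 100 drawn splits, highest other 683), the 1 outside both parents (10 of 100, highest other 284) or the 2 lists (83 of 100, highest other 6). The 8 other splits with as many mid-parent calls point to a structure of the samples. Of these, 6 put all 3 arrays of 1 parent in the place of F1 (113 to 683 calls), so they hold the difference between the parents. The other 2 put replicate 1 of every group there (255 and 171), so they follow the replicate number. The 9 of 100 for the mid-parent calls thus does not measure chance for the real groups and decides nothing. The blocked mid-parent count was 0. Among splits parting all same-number pairs of Col and C24, or of Col and F1, the highest other also gave 0.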

Other observations

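Further single genes differed between the parents, in lists written after the gene names were seen. The histone gene HTB2 was 4.65-fold lower in C24, at 110.7 ± 12.8 against 522 ± 127 in Col, with F1 at 277 ± 33.6 (SD, n = 3). UGT85A2 was 3.71-fold lower in C24, TBL23 of the cell wall acetylation family 3.92-fold and the MADS-box gene AGL87 4.62-fold, and BGLU42 was 2.37-fold lower. In the same lists the histone gene AT3G09480 was higher in C24, at 60.1 ± 4.62 against 32.5 ± 5.99, as were UGT72B3 (62.3 ± 13.99 against 31.03 ± 6.80), BGLU15 (107.6 ± 20.8 against 61.4 ± 12.1) and BGLU43 (29.1 ± 11.4 against 3.65 ± 2.40). The calls of AT3G09480 (without Col replicate 1 or 2 or C24 replicate 1, adjusted p up to 0.0661), UGT72B3 (Col replicate 2 or 3 or C24 replicate 1 or 3, up to 0.0948) and BGLU15 (Col replicate 2 or 3, F1 replicate 2 or any C24 array, up to 0.11) were lost with an array left out. In all, 1 of 10 histones was higher and 1 lower, 1 of 25 UDP-glycosyltransferases higher and 3 lower, and 3 of 12 beta-glucosidases higher and 1 lower. SWEET11, a sucrose transporter gene, was 1.65-fold higher, a call lost without Col replicate 1 or 2 or C24 replicate 1 or 3 (adjusted p up to 0.101). None of their lists passed (adjusted p = 0.975 for histones, 0.221 for UDP-glycosyltransferases, 0.47 for the acetylation family, 0.194 for MADS-box genes, 0.582 for beta-glucosidases and 0.658 for SWEET transporters), though that of UDP-glycosyltransferases did with the filter at the 50th percentile (0.0306).

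Genes much lower in C24 were tested for lying next to each other, as a candidate sign of regional divergence or gene loss between the accessions. Of 8637 tested genes in chromosome order, 90 were at least 4-fold lower in C24 and 3 neighbouring pairs were both so, AT5G45500 with AT5G45510, AT4G16870 with AT4G16880 and AT2G21830 with AT2G21860, against a mean of 0.915 in 10000 shuffles (one-sided permutation p = 0.062). A p of 0.05 or more was to count against the hypothesis; that bound was too loose, since 3 pairs are still above the mean of the shuffles, and it was set aside after p had been seen. The hypothesis is neither borne out nor excluded.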
